A study of Mus musculus with 4 samples.

How the data were processed

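Msi1 CLIP-seq was analysed in 4 libraries of mouse intestinal epithelial cells, 2 wild-type and 2 TRE-Msi1, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, wild-type samples were crypts of control mice and TRE-Msi1 samples were total epithelial cells of mice given doxycycline for 24 h. Cells were irradiated at 265 nm with 2 pulses of 400 mJ per cm2, and material near 50 kD was cut from the membrane, per the labels' protocols. The protocols speak of 2 mice for each group, so the 2 libraries of a group were treated as separate samples. With 2 libraries per group the spread between them is poorly known.

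Per the submitters' processing notes, Bowtie (a short-read aligner), HOMER (a set of programs that includes a peak finder) and the build mm9 were used. Versions, settings, read filters and the role of each program are not given in the sources used here. The deposited files hold one peak list per library, so peaks were called or at least listed per library and not on pooled samples. Each row gives a chromosome, start, end, strand and the authors' score, and the deposited files do not state the unit of that score. The deposited score is 0 for every peak of wild-type replicate 1, a whole number of at least 3 in wild-type replicate 2 and of at least 4 in TRE-Msi1 replicate 2, and a value with 1 decimal of at least 1.5 in TRE-Msi1 replicate 1. Median peak widths were 74, 75, 40 and 75 bp in wild-type replicates 1 and 2 and TRE-Msi1 replicates 1 and 2. Whether the settings of the peak calling differed between libraries is not given in the sources used here, but the TRE-Msi1 replicate 1 list stands apart in width and score format. Its 189594 peaks, and each fold or overlap that uses them, can therefore carry an effect of the calling as well as of the sample. Scores were used to rank or filter peaks within a list, with ties kept in order of position. The one exception is a count of peaks scored at least 4, 10 or 20 in the replicate 2 lists of both groups, in the closing section, which assumes that these scores share a unit. Where wild-type replicate 1 had to be ranked, the order of its rows stood in for the score. Row order and score were closely related in the other 3 lists (Spearman's rho across peaks -0.963 in wild-type replicate 2, -0.989 in TRE-Msi1 replicate 1 and -0.905 in TRE-Msi1 replicate 2).

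Overlap was counted on the same strand with at least 1 bp in common. Chance overlap was measured by 100 placements of a list at random within each chromosome, which ignore where genes lie, and by 100 shifts of each peak by 5000 to 50000 bp, which keep it near its own locus (20 shifts where peaks within 500, 2000 or 10000 bp were counted). Chromosome lengths were taken as the highest peak end in any of the 4 lists. Peak numbers were compared on the log2 scale with a two-sided exact permutation test. Shares carry 95% Wilson intervals, which treat peaks as independent and cover counting error only. The overlap code was tested on simulated lists of the lengths of the TRE-Msi1 lists, where planted overlaps of 5, 20 and 50% were recovered as 4.98, 19.9 and 49.9% above chance. Its counts differed from those of bedtools for 0 peaks in 36 comparisons. Coordinates are 1-based. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

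The groups, tests, main overlap rule, most alternatives and the rule for named regions were fixed before the data were examined. Without annotation, that rule takes the 10 shared TRE-Msi1 peaks without a wild-type peak and the 5 peaks of all 4 libraries with the highest mean percentile of the score over the TRE-Msi1 lists. Alternatives were the top 25% of each list, lists of equal length, fewer chromosomes, reciprocal overlap of 50%, either strand, merging within 50 bp, leaving out each library and a replicate block. Those added after seeing the data were resizing peaks to 75 bp, distances of 500 and 2000 bp, the minus strand alone, identical intervals counted once and local shifts. The number of planned results not computed is 4: the share of peaks in 3' UTRs, the Musashi motif in peaks, tests of gene lists and the number of genes with shared exonic peaks. They need a genome or annotation of mm9, which was not used here, and coordinates were not converted between builds.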

Results

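Positions on RNA recovered with Musashi-1 (Msi1), an RNA-binding protein, were mapped in mouse intestinal epithelial cells. The assay was CLIP-seq, in which ultraviolet light joins a protein to the RNA it touches, the protein is pulled down with an antibody (here against Msi1) and the attached RNA fragments are sequenced. There were 4 libraries: 2 from wild-type mice without doxycycline and 2 from TRE-Msi1 mice, which carry a doxycycline-driven Msi1 transgene, after 24 h of doxycycline. Each library has its own list of peaks, with coordinates of the mouse build mm9 and a strand. The wild-type lists held 4863 and 5578 peaks (replicates 1 and 2) and the TRE-Msi1 lists held 189594 and 40776. Read numbers per library are not given in the sources used here, so the depth behind each list is unknown. All 4 libraries are Msi1 CLIP-seq, with no background control among them. A peak is therefore a called position and was not shown to be bound by Msi1. The design sets the transgenic samples against the wild-type ones, in a study that treats the Msi family as drivers of intestinal cancer. It asks where peaks are called on RNA after induction and which of those positions already have a peak without it. Regions are named by position, because no mm9 gene annotation was used here.

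After induction, many more positions on RNA were called. The geometric mean list was 16.9-fold longer in TRE-Msi1 than in wild-type epithelium, and both TRE-Msi1 lists were longer than both wild-type lists. On the log2 scale the mean peak number was 16.42 ± 1.57 (SD, n = 2) in TRE-Msi1 and 12.35 ± 0.14 (SD, n = 2) in wild-type libraries, a difference of 4.08. The 2 wild-type lists differed 1.15-fold in length and the 2 TRE-Msi1 lists 4.65-fold, so the size of the increase depended on the TRE-Msi1 library used. It was 2.97 on the log2 scale without TRE-Msi1 replicate 1 and 5.19 without TRE-Msi1 replicate 2. Together the peaks covered 355.9 and 415.4 kb in the wild-type lists, against 7583 kb (replicate 1) and 3022 kb (replicate 2) in the TRE-Msi1 lists. A two-sided exact permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. Genotype, doxycycline and the cells taken (crypts in wild-type mice, total epithelium in TRE-Msi1 mice) changed together and cannot be separated, and peak numbers could not be scaled for depth. The TRE-Msi1 replicate 1 list also differs in form, with 40 bp peaks against 74 to 75 bp and scores with 1 decimal, so its length and its overlaps are open to a difference in peak calling.

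**Figure D1:**
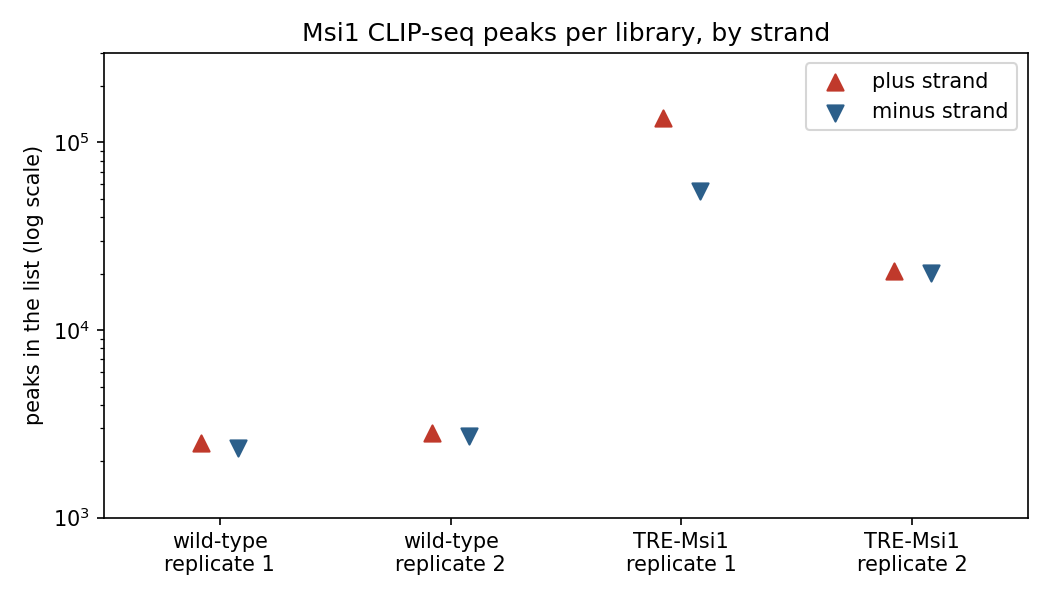
Number of peaks on the plus strand (upward triangles) and the minus strand (downward triangles) in each of the 4 libraries, on a log axis. The wild-type libraries and TRE-Msi1 replicate 2 have nearly equal numbers on both strands, whereas TRE-Msi1 replicate 1 has 134288 plus-strand and 55306 minus-strand peaks.

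Along the genome, peaks were densest on chromosome 11 in all 4 libraries and sparsest on the X chromosome, among the numbered chromosomes and X. On chromosome 11 the wild-type lists held 3.28 and 3.45 peaks per Mb, 1.74-fold and 1.58-fold their autosomal level. TRE-Msi1 replicate 2 held 23.4 per Mb there, 1.47-fold its autosomal level, and TRE-Msi1 replicate 1 held 88.8 per Mb, 1.25-fold. Chromosome 19 came next in 3 libraries, at 1.71-fold and 1.54-fold the autosomal level in the wild-type lists and 1.44-fold in TRE-Msi1 replicate 2, whereas in TRE-Msi1 replicate 1 it stood at 1.06-fold. The X chromosome reached 0.543 and 0.468 of the autosomal density in the wild-type lists, 0.481 in TRE-Msi1 replicate 2 and 0.894 in TRE-Msi1 replicate 1. Peaks per Mb varied over the autosomes with a coefficient of variation of 27.1% and 21.3% in the wild-type lists, 16.8% in TRE-Msi1 replicate 2 and 8.04% in TRE-Msi1 replicate 1.

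The strand of the peaks also set TRE-Msi1 replicate 1 apart. Plus-strand peaks made up 70.8% of its list (95% Wilson interval 70.6 to 71.0%), against 51.5% and 50.9% in the wild-type lists and 50.9% in TRE-Msi1 replicate 2. The share lay between 68.9% and 72.3% on each of the 20 numbered and X chromosomes. Its peaks within 500 bp of a same-strand peak of another library were 52.7% plus-strand (51.8 to 53.6%, n = 11374 peaks), and those with no such neighbour on either strand 72.0% (71.8 to 72.2%, n = 177175 peaks). With 50000 bp as the distance the shares were 67.7% and 73.2%. Wilson intervals here and elsewhere cover counting error only.

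**Figure D2:**
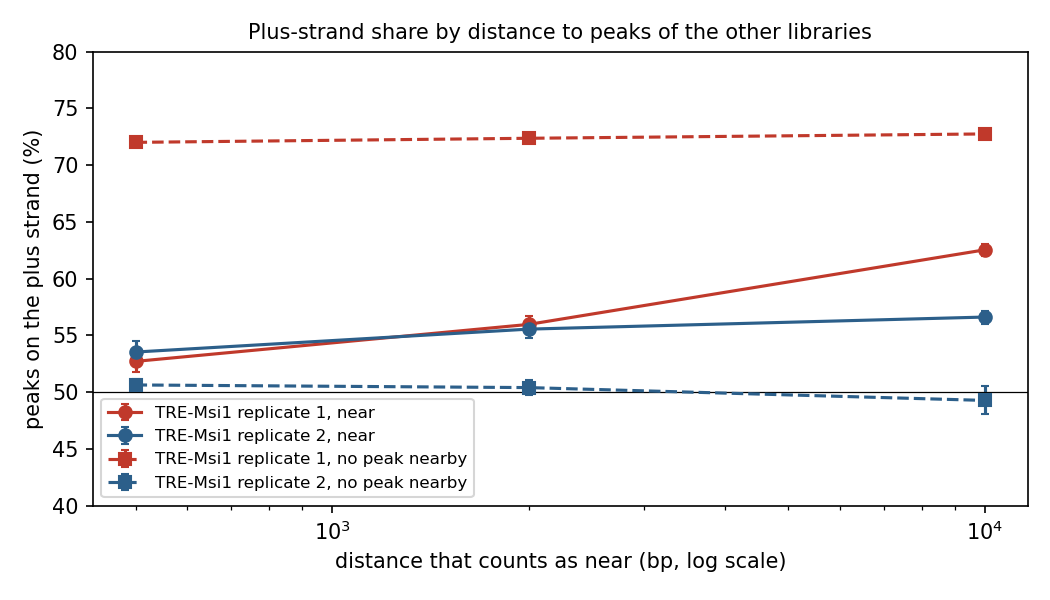
Share of peaks on the plus strand (%, vertical axis) against the distance in bp that counts as near (log axis), for the TRE-Msi1 libraries. Solid lines show peaks with a same-strand peak of another library within that distance, dashed lines peaks with none on either strand, and bars 95% Wilson intervals; from 500 to 10000 bp TRE-Msi1 replicate 1 has 72.0 to 72.7% on the dashed line and 52.7 to 62.5% on the solid line.

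Within each group, the replicates shared a small part of their positions, far above chance placement. Neither random placements nor local shifts are confined to transcribed RNA. The excess therefore does not separate shared Msi1 positions from RNA that is abundant in both libraries. In the wild-type epithelium 516 of the 4863 peaks of replicate 1 overlapped a replicate 2 peak on the same strand by at least 1 bp, which is 10.6% (9.78 to 11.5%), against a mean of 0.0269% over 100 random placements within chromosomes. In TRE-Msi1 epithelium 2310 of the 40776 peaks of replicate 2 overlapped a peak of replicate 1, or 5.67% (5.44 to 5.89%), against 0.408% for random placements (highest 0.486%) and 0.728% when peaks were shifted locally by 5000 to 50000 bp. Sharing was concentrated in the highest-scoring peaks. In the top 10% of the wild-type replicate 2 list, ranked by the authors' score, 46.8% of peaks were shared with wild-type replicate 1, and 2.69% in the bottom 10%. In the TRE-Msi1 replicate 2 list the shares in replicate 1 were 20.6% (19.4 to 21.8%) and 1.96%. Read from TRE-Msi1 replicate 1, 2.07% of its top 10% and 0.575% of its bottom 10% were shared with replicate 2. The TRE-Msi1 overlap depended on the rule, at 1.88% with a reciprocal overlap of 50% and 19.2% when any same-strand peak within 500 bp counted. Local shifts gave 6.12% within that distance.

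**Figure D3:**
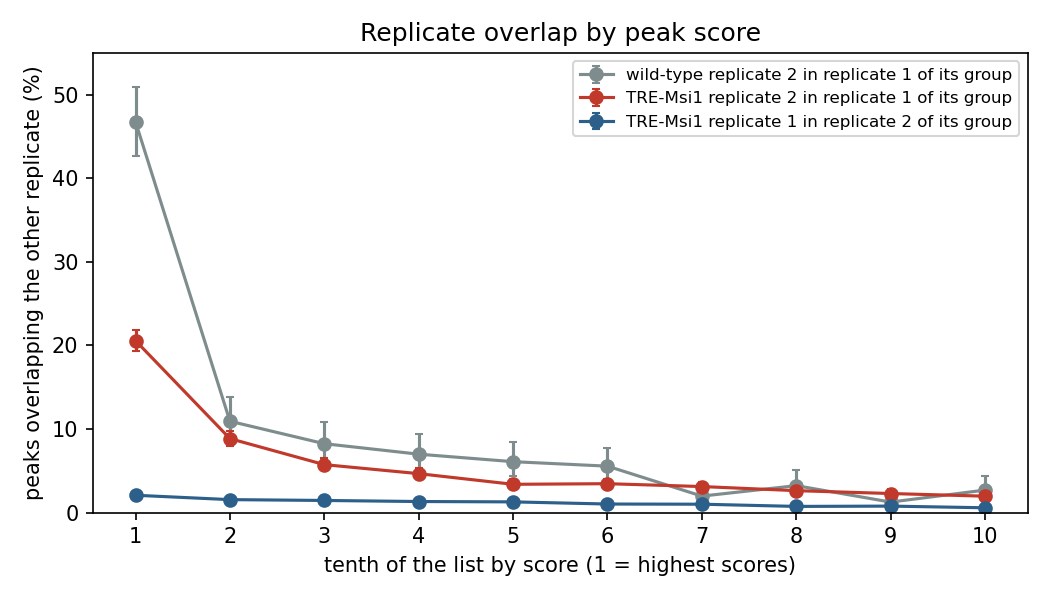
Share of peaks that overlap the other replicate of the same group (%, vertical axis) in 10 equal parts of each list by score, from the highest (1) to the lowest (10); bars are 95% Wilson intervals. The first and last parts stand at 46.8% and 2.69% for wild-type replicate 2, 20.6% and 1.96% for TRE-Msi1 replicate 2, and 2.07% and 0.575% for TRE-Msi1 replicate 1. Ties in score are divided by position.

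Most peaks of wild-type replicate 1, and a minority of those of wild-type replicate 2, overlapped a peak in at least 1 TRE-Msi1 library. Of the peaks of wild-type replicate 1, 2838 (58.4%) overlapped a peak in at least one TRE-Msi1 library and 756 (15.5%, 14.6 to 16.6%) in both, with random placements at 0.0103% for both. Of the peaks of wild-type replicate 2, 1128 (20.2%) overlapped a peak in at least one TRE-Msi1 library and 258 (4.63%, 4.10 to 5.21%) in both, with random placements at 0.0115%. The mean share found in both was 10.1 ± 7.72% (SD, n = 2), and the intervals of the wild-type libraries did not overlap. Against single TRE-Msi1 lists, wild-type replicate 1 peaks were found at 43.1% in replicate 1 and 30.8% in replicate 2, and wild-type replicate 2 peaks at 9.25% and 15.6%. In the top 10% of wild-type replicate 2 by score, 34.2% of peaks were found in TRE-Msi1 replicate 1 and 46.8% in TRE-Msi1 replicate 2. When a TRE-Msi1 list was dropped, peaks had to match only the other list. The mean share found was then 23.2% without TRE-Msi1 replicate 1 and 26.2% without TRE-Msi1 replicate 2. Cutting all lists to 4863 peaks lowered the mean share found in both to 1.69%. With a reciprocal overlap of 50%, the share found in both fell to 3.80% for wild-type replicate 1 and 0.968% for wild-type replicate 2.

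Peaks of TRE-Msi1 replicate 2 that replicate 1 shared overlapped wild-type peaks more often than unshared peaks did. Of the 2310 shared peaks of TRE-Msi1 replicate 2, 802 (34.7%, 32.8 to 36.7%) overlapped a wild-type peak, against 1315 (3.42%, 3.24 to 3.60%) of its 38466 unshared peaks. Wild-type replicate 1 carried most of this, at 30.4% of shared and 2.18% of unshared peaks. With wild-type replicate 2 alone the shares were 10.5% and 1.66%. Shared and unshared peaks were not matched on score. Sharing itself rose with score, from 1.96% in the bottom 10% of TRE-Msi1 replicate 2 to 20.6% in the top 10%. Whether the contrast holds at equal score was not tested. A total of 143 peaks (138 distinct intervals) were present in all 4 libraries. The 5 with the highest score percentiles, averaged over the TRE-Msi1 lists, lay on chromosome 2 at 22600328 to 22600402 (minus strand, mean percentile 99.98), chromosome 16 at 35981706 to 35981780 (minus, 99.98), the mitochondrial genome at 854 to 928 (plus, 99.97), chromosome 13 at 97960440 to 97960514 (minus, 99.94) and chromosome 9 at 78023062 to 78023136 (minus, 99.92).

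Positions shared by both TRE-Msi1 libraries without an overlapping wild-type peak numbered 1508, or 65.3% (63.3 to 67.2%) of the 2310. Random placements gave a mean of 164.4 (highest 215) and local shifts 280.4 (highest 334), so the observed number was 9.17 and 5.38 times these means. Placed peaks almost never met a wild-type peak (mean 0.0162% for wild-type replicate 1 and 0.0185% for wild-type replicate 2). The folds therefore reflect the overlap between the TRE-Msi1 lists and do not measure absence from the wild-type lists. The 1508 peaks (1471 distinct intervals) formed 1216 loci when peaks up to 10 kb apart on a strand were joined. Of the loci, 227 held at least 2 peaks, with identical intervals counted separately. The highest mean percentiles belonged to chromosome 17 at 39985078 to 39985152 (plus, 99.94), the mitochondrial genome at 363 to 437 (plus, 99.65), chromosome 11 at 99290194 to 99290268 (minus, 99.48), chromosome 1 at 193759977 to 193760051 (plus, 99.36) and chromosome 6 at 128626093 to 128626167 (plus, 99.25). They were followed by chromosome 19 at 5801763 to 5801837 (minus, 99.09), chromosome 6 at 40718930 to 40719004 (plus, 98.91), chromosome 2 at 143768311 to 143768385 (plus, 98.89), chromosome 2 at 117074149 to 117074223 (plus, 98.82) and chromosome 2 at 143767991 to 143768065 (plus, 98.55). In 8 of these 10 regions a wild-type peak lay 9 to 118 bp away on the same strand. The exceptions were the regions at 193759977 on chromosome 1 and 117074149 on chromosome 2, where the nearest wild-type peak was 26.3 and 22.6 kb away. The chromosome 17 peak lies at 39983316 to 39985152, a stretch that supplied 5 of the first 10 peaks listed in each wild-type library. The mitochondrial genome supplied 3 of those 10. These 2 places therefore ranked high without induction too. Among all 1508 peaks, 569 (37.7%, 35.3 to 40.2%) had a wild-type peak within 500 bp, against 1.46% of locally shifted peaks, and 808 (53.6%, 51.1 to 56.1%) within 2000 bp, against 4.74%. The number fell to 588 of 766 shared peaks with a reciprocal overlap of 50% and to 26 of 102 with lists cut to 4863 peaks. In the cut lists the other 76 shared peaks overlapped a wild-type peak, so the majority without one did not hold there. With TRE-Msi1 replicate 2 alone there were 38659 peaks without a wild-type peak, and with TRE-Msi1 replicate 1 alone 187244.

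Some regions held several such peaks, and these were picked out after their values were seen. The largest group lay on the minus strand of chromosome 3 at 65183598 to 65191677, with 7 shared peaks that overlapped no wild-type peak, although wild-type replicates 1 and 2 had 3 and 2 other peaks in the region. A region on the minus strand of chromosome 9 at 66870355 to 66880346 held 6, with 1 peak in wild-type replicate 1 and 0 in wild-type replicate 2. There were 5 each on chromosome 12 at 70474515 to 70476993 (plus), chromosome 7 at 87857344 to 87858394 (minus) and chromosome 9 at 75346789 to 75347862 (minus). Of these 3 regions, the first had 1 peak in wild-type replicate 2 and the second 1 peak in wild-type replicate 1. The last had none in either wild-type list. Shared peaks are counted here in the TRE-Msi1 replicate 2 list, with identical intervals counted separately. In the 5 regions, in the order given, TRE-Msi1 replicate 1 had 16, 10, 13, 5 and 3 peaks.

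In lists of equal length, how much 2 libraries shared varied from pair to pair, and the pairs with TRE-Msi1 replicate 1 shared least. With the 4863 highest-ranked peaks of each list, the wild-type pair shared 10.4% and the TRE-Msi1 pair 2.16% of peaks. Between groups, wild-type replicate 1 shared 15.3% with TRE-Msi1 replicate 2 and 3.41% with TRE-Msi1 replicate 1, and wild-type replicate 2 shared 7.98% and 2.45% with these. The mean was 6.26% within groups, from a wild-type pair above and a TRE-Msi1 pair below the mean of 7.29% between groups. A two-sided exact permutation test over the 3 possible pairings (p = 1) cannot go below p = 0.333, so whether groups differ in this was not resolved. The wild-type replicate 1 list enters whole here, since it is the shortest, so its scores, all 0, play no part.

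**Figure D4:**
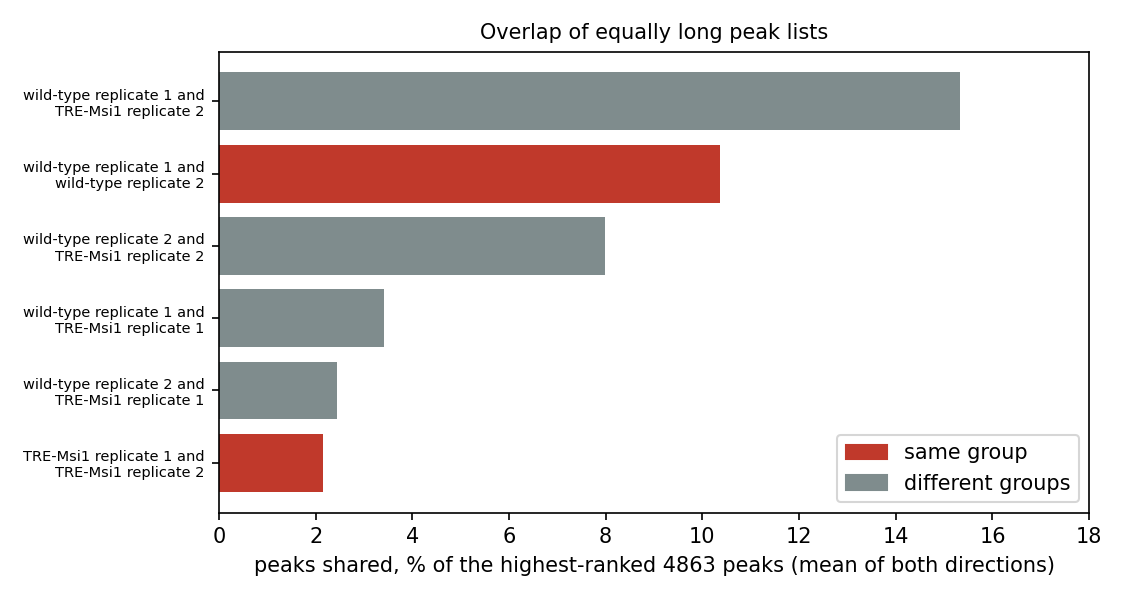
Share of peaks in common (%, horizontal axis, mean of both directions) for the 6 pairs of libraries, each list cut to its 4863 highest-ranked peaks; red bars are pairs of the same group and grey bars pairs of different groups. The 3 pairs with TRE-Msi1 replicate 1 share 2.16 to 3.41%, and the other 3 pairs 7.98 to 15.3%.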

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

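All tests below were added after the peak lists had been examined; those of peak width, nearby positions, the score floor and depth were named before their own results were seen, and those of strand loss, signal outside other regions, even coverage and weak peaks afterwards. Plus-strand peaks were 70.8% of the TRE-Msi1 replicate 1 list, above the wild-type lists (51.5% and 50.9%), and the balance of strands was not what any comparison of the groups measured, where strand only decided which peaks overlap. In the top 10% of that list by score they were 74.96% (74.3 to 75.6%). A strand lost at random over the whole list would leave at least 20.8% of the peaks near other libraries' peaks with a neighbour on the opposite strand only, and 8.41% (7.94 to 8.92%) had one, which argues against it. Extra plus-strand signal outside regions with peaks in other libraries remains a candidate explanation, since the plus share was 52.7% beside same-strand peaks of other libraries and 72.0% away from them. Even coverage of the genome by the extra peaks met the criterion first set but stays open: the coefficient of variation of peaks per Mb over autosomes was 7.98% for plus-strand and 8.90% for minus-strand peaks, a gap of 0.92 percentage points with a 95% jackknife interval, added after the values were seen, of -0.80 to 2.65. No biological explanation of this pattern was tested, since the design names none that would act on one strand.

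The same library held 2568 peaks on Y chromosome sequences, 1.35% of its list (1.30 to 1.41%), against 2 and 4 peaks (0.0411% and 0.0717%) in the wild-type lists and 11 (0.0270%) in TRE-Msi1 replicate 2. This stood out because it exceeds the wild-type level on sequences that no comparison looked at by themselves. These peaks are part of the list lengths, and without Y and other sequences outside the numbered and X chromosomes the log2 difference between groups was 4.07.

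The small overlap of the TRE-Msi1 libraries (5.67%) was set against technical explanations. The narrower peaks of replicate 1 are unlikely to account for it, since resizing all peaks to 75 bp gave 7.38%. Weak peaks in replicate 2 may contribute, because 20.6% of its top 10% were shared with the whole replicate 1 list, which still leaves most unshared. With both lists cut to stronger peaks, the overlap was 6.10% in the top 25% and 2.10% in the top 4863 peaks. These cuts also remove replicate 1 peaks that could match, so they do not decide how much weak peaks of replicate 2 contribute. Calls at nearby positions may contribute too, because a peak within 500 bp was 3.13-fold more frequent than after local shifts. That count includes the direct overlaps, themselves 7.79-fold above local shifts. It therefore does not give the part that comes from nearby calls alone. No biological explanation was tested, since both libraries belong to one group.

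For the longer TRE-Msi1 lists, the lowest score that a list admits is unlikely to be the whole cause in replicate 2. Against wild-type replicate 2 it held 9.63-fold (9.33 to 9.94) as many peaks scored at least 4, 6.13-fold (5.78 to 6.50) at 10 and 6.03-fold (5.26 to 6.91) at 20, and its own lowest score was the higher one (4 against 3). This takes both scores as one unit, which no source states, though both are whole numbers with a median of 6. Sequencing depth cannot be told apart from induction: read numbers are unknown, and the 7.31-fold excess over wild-type replicate 2 could follow either. Doxycycline induction of Msi1 and the use of total epithelium in place of crypts also stay open, untested.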

How the results depend on the processing

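Settings chosen after seeing the data were the 75 bp width, the distances of 500 and 2000 bp, the minus strand alone and identical intervals counted once; the rest were planned. The longer TRE-Msi1 lists kept their direction under all 9 alternatives, from 2.97 to 5.19 on the log2 scale when each library was left out. Leaving out a library or using a replicate block could not reverse it, since both TRE-Msi1 lists were longer than both wild-type lists. With the replicate number as a paired block the difference was 4.08 (exact sign-flip p = 0.5, the smallest that 2 pairs allow); nothing in the labels says that numbers pair the samples, and same-numbered libraries of the 2 groups shared 5.70% of equally long lists against 8.89% for the crossed numbers. The TRE-Msi1 overlap (5.67%) was 6.10% in the top 25% of each list, 2.10% in lists of equal length, 1.88% with reciprocal overlap of 50%, 7.38% at 75 bp, 19.2% within 500 bp, 34.0% within 2000 bp and 6.32% on the minus strand. The wild-type overlap (10.6%) was 17.2% in the top 25%, 8.16% with reciprocal overlap, 19.2% within 500 bp and 27.1% within 2000 bp. The number of shared TRE-Msi1 peaks without a wild-type peak (1508) was 346 in the top 25%, 26 in lists of equal length, 588 with reciprocal overlap, 4370 within 500 bp, 7893 within 2000 bp and 808 on the minus strand. It was 2067 without wild-type replicate 1 and 1608 without wild-type replicate 2. Leaving out a TRE-Msi1 library removes the sharing rule, so every peak of the other list without a wild-type peak counts. This gave 38659 without TRE-Msi1 replicate 1 and 187244 without TRE-Msi1 replicate 2. The share of wild-type peaks found in both TRE-Msi1 libraries (10.1%) was 1.69% in lists of equal length, 34.8% within 500 bp and 46.5% within 2000 bp. It was 4.63% without wild-type replicate 1 and 15.5% without wild-type replicate 2. Without TRE-Msi1 replicate 1 or 2 it became the share found in the other, at 23.2% and 26.2%. With reciprocal overlap the share found in both was 2.39%, a shift smaller than the wide SD between the wild-type libraries (7.72). The share nevertheless fell in each, from 15.5% to 3.80% and from 4.63% to 0.968%. For these 4 results in this order, the shift stayed within the error, or within 1.5 times for the count, in 3, 6, 7 and 9 alternatives. It was larger in 7, 4, 8 and 5 alternatives. The 9 include this reciprocal overlap. They also include the omission of each wild-type library, which cannot shift a mean of 2 values beyond their SD. Shorter lists, wider distances, a single strand and the omission of a TRE-Msi1 library change the counts by construction. The share of shared TRE-Msi1 peaks without a wild-type peak is not fixed in that way. It was 1508 of 2310 in the full lists and 26 of 102 in lists of equal length. A 40 bp peak inside a 75 bp peak barely reaches a reciprocal overlap of 50%. The cause of the other shifts was not tested. The top 25% and equal lengths fix the number of peaks and were not run for it. Alternatives of the 4 results that need an mm9 genome or annotation were not run. Unknown depth limits every absence: a position missing from a short list was not shown to be unbound.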

Other observations

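One short region stood among the first-listed peaks of all 4 libraries. On the plus strand of chromosome 17 at 39983316 to 39985152 (1837 bp) there were 6 peaks in each wild-type library, 10 in TRE-Msi1 replicate 1 and 6 in TRE-Msi1 replicate 2. It supplied 5 of the first 10 peaks listed in each wild-type library, 3 in TRE-Msi1 replicate 1 and 4 in TRE-Msi1 replicate 2. The region was chosen after its values were seen, and it contains the first-ranked of the 10 named TRE-Msi1 peaks. What is annotated there was not examined here.

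The mitochondrial genome held 11 and 12 peaks in wild-type replicates 1 and 2, 17 in TRE-Msi1 replicate 1 and 15 in TRE-Msi1 replicate 2. Of the first 10 peaks listed, 3 were mitochondrial in each wild-type library, 0 in TRE-Msi1 replicate 1 and 4 in TRE-Msi1 replicate 2.

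Shared TRE-Msi1 peaks without a wild-type peak were also densest on chromosome 11 and sparsest on the X chromosome, at 1.78-fold and 0.447 of the autosomal level. Chromosome 19, with 48 of these peaks, stood at 1.33-fold, beside 1.71-fold and 1.54-fold in the wild-type lists, 1.06-fold in TRE-Msi1 replicate 1 and 1.44-fold in TRE-Msi1 replicate 2, differences that were not tested. Of these peaks 53.6% lay on the minus strand (51.1 to 56.1%).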
